A study of Caenorhabditis elegans with 2 samples.

How the data were processed

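ChIP-seq against eGFP-tagged SNPC-4 was carried out in whole L1 larvae of Caenorhabditis elegans strain OP179, in 2 biological replicates that form 1 group. Fragments of 150 to 350 bp were selected, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. Each replicate has a relaxed list of 30000 peaks and the series has a pooled relaxed list of 30000, each made by the authors from alignments and a control alignment, per the deposited notes that accompany the lists. A thresholded list of 2347 peaks was derived by the authors from the pooled and the replicate lists by the irreproducible discovery rate, per the same notes. All lists come on builds ce10 and ce11, and ce11 was used throughout except where stated. The labels do not give read numbers, so depth is unknown and no counting error of a signal can be given.

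The deposited signal of a peak (never negative) is the authors' enrichment value, and its scale is not given in the sources used here. It was used only within a list. The deposited −log10 q was at its maximum of 2.95 in all 2347 thresholded peaks, so peaks were ranked by signal. Other deposited columns give coordinates and the distance of the summit from the peak start, per the file layout. In the thresholded list 1922 peaks (81.9%) had the same width of 344 bp, and a summit is the start of the peak plus the deposited distance. No column of another sample was present.

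Genes and 5′ ends were taken from the Ensembl 115 annotation of the same assembly, and names from RefSeq. Classes follow the annotated biotype, with SL RNA genes separated from snRNA genes by name. The snRNA biotype includes mir-1831, which lies inside a U1 gene. Mitochondrial peaks were left out of all tests; only for the distribution over chromosomes had this been set in advance.

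Replicates were compared over the N highest peaks of each, with N the number of thresholded peaks, a match being a summit within 100 bp. Gene classes were compared with 10000 random rotations of the peaks along each chromosome, which keep the spacing of peaks. The smallest two-sided p these give is 0.0002 before adjustment. Other tests were Fisher's exact test, exact binomial and McNemar tests and permutation with 100000 resamples, and adjustment was by Benjamini-Hochberg at 0.05. Intervals are exact 95% binomial intervals over genes and cover counting error only. Because replicates were combined by the authors in the thresholded list, tests over genes or peaks describe these lists and not the spread between animals.

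Named genes followed a rule set before the data were examined. It takes the gene nearest to each of the 25 highest peaks, the 3 genes with the highest peak in each small RNA class, up to 4 members with the highest peak in each of 20 protein-coding lists, and snpc-4 and unc-119. Outside that rule, sls-2.9, F08H9.10, Y67A10A.14, sup-39, mir-1831, T27E4.12, T27E4.22, T21B4.t1, T03E6.t1, F08G2.9, ZK897.4 and H27M09.6 are named for a shared peak, smy-3 for its type, and the sites among the closing observations were chosen after their values were seen. Mitochondrial genes under the rule are not named, and a nuclear gene under it is not reported here.

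The spliceosomal types of snRNA genes were assigned from short sequences in the transcript (U1 ACTTACCTG, U2 GTAGTATC, U4 AGCTTTGCGC, U5 CTTTTAC, U6 ACAGAGA). The matrix of 20 bases was fitted by expectation maximisation to 65 upstream sequences of 100 bp, seeded by their most frequent word of 8 bases. A match was a score at or above the 99th percentile of 2344 flanking windows on chromosomes I, III and V, and tests used chromosomes II, IV and X. A position was called single-copy where its 36-base word occurs once in the genome.

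The methods were tested on simulated data. In 20 random peak sets over 46890 genes, 0 of 200 class tests were called. With peaks planted at 3 classes all 3 were recovered, and 1 other class, piRNA genes, was called, below its rotation mean. A planted list and a planted word were recovered. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

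Alternatives were other windows, summit distances and numbers of peaks, build ce10 for the replicates, the upper part of the thresholded list (1173 peaks by signal), gene bodies in place of starts, tandem genes within 1 kb counted as a locus, uniform placement with 1000 draws, leaving out peaks near tRNA, snRNA or SL RNA starts, and each replicate left out in turn by taking the N highest peaks of the other one.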

Results

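The data are chromatin immunoprecipitation with sequencing (ChIP-seq) profiles of SNPC-4 in Caenorhabditis elegans larvae at the first stage (L1). SNPC-4 is the worm homolog of SNAP190, the largest subunit of the small nuclear RNA activating complex (SNAPc), which binds the promoters of small nuclear RNA (snRNA) genes. The strain, OP179, carries a transgene of snpc-4 joined to enhanced green fluorescent protein (eGFP) in an unc-119 mutant background. Whole worms of pooled sexes were used, and the 2 samples are biological replicates 1 and 2 of a single group. No second condition was profiled in these samples, so the comparisons are between replicates, between gene classes and between regions of the genome. Sequencing depth is unknown, because the files hold peaks and no read counts. All coordinates are on build ce11, and signal is the authors' own value for each peak, used only to rank and describe peaks within a list.

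The thresholded list of the series held 2347 peaks, of which 2319 lay on the 6 nuclear chromosomes and 28 on the mitochondrial genome. Signal ranged from 32.3 to 6125 with a median of 53.3, and the 100 highest peaks held 51.4% of the summed signal. These 2347 peaks were the 2347 highest of the 30000 in the pooled relaxed list. Of the nuclear peaks, 1539 (66.4%) had their summit in intergenic sequence, which makes up 34.6% of the nuclear genome, and 16 (0.690%) had it in a coding exon, against 24.6% of the genome.

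The first comparison asked how far the replicates place their peaks at the same sites. The snRNA, SL RNA and small nucleolar RNA (snoRNA) genes that led replicate 1 also led replicate 2. W05B2.8, a U6 snRNA gene, ranked 2 in replicate 1 and 1 in replicate 2, and sls-2.4, a gene for the spliced leader RNA SL2, ranked 1 and 3. Among the 2347 highest peaks of each replicate, 1474 of the 2326 nuclear summits of replicate 1 (63.4%) had a summit of replicate 2 within 100 bp. Random rotations of the peaks along each chromosome gave a mean of 0.477% and a maximum of 11.01%, so the one-sided p was 0.0001, the smallest that 10000 rotations can give. For the 100 highest peaks of each replicate the share was 90.7% (78 of 86 nuclear summits). Across the 1474 matched peaks, Spearman's rho of signal between the replicates was 0.735. That value is across peaks, which are not independent replicates, and has no p-value. Of the 2319 thresholded nuclear peaks, 2159 (93.1%) had a summit within 100 bp in both replicates' relaxed lists. The thresholded list was derived from these same replicates by their reproducibility, so this share is partly built in and is not independent support.

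The second comparison asked which classes of gene carry SNPC-4 at their start. Genes for spliced leader RNAs (SL RNA), which supply the leader that is trans-spliced onto worm messenger RNAs, and genes for spliceosomal snRNAs were bound most often. A summit lay within 250 bp of the 5′ end of 14 of 30 SL RNA genes (46.7%, exact 95% binomial interval 28.3 to 65.7%) and of 42 of 99 snRNA genes (42.4%, 32.5 to 52.8%). The snoRNA genes, whose products guide the modification of ribosomal RNA, followed with 85 of 346 (24.6%, 20.1 to 29.5%), and transfer RNA (tRNA) genes with 101 of 612 (16.5%, 13.6 to 19.7%). Rotation of the peaks gave means of 0.339 SL RNA genes, 1.11 snRNA genes, 4.14 snoRNA genes and 6.98 tRNA genes. The observed counts were 41.3-fold, 37.9-fold, 20.5-fold and 14.5-fold higher than these means.

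Protein-coding genes were bound less often, 1016 of 19973 (5.09%), which was 4.44-fold above rotation, and genes of the other non-coding class reached 467 of 8058 (5.12-fold). These 467 genes rest on 374 peaks, and 140 of them share theirs with a small RNA gene. For microRNA genes the count was 10 of 261 (3.29-fold). Genes for PIWI-interacting RNAs (piRNAs) were bound below rotation, 63 of 15363 against a mean of 162.3 (0.388-fold), and pseudogenes were too, with 13 of 2128 (0.563-fold). None of 20 ribosomal RNA genes had a summit, where rotation gave 0.195, and the median share of 36-base words around their starts that occur once in the genome was 0. The two-sided permutation test by rotation with Benjamini-Hochberg adjustment over the 10 classes gave adjusted p = 0.000286, the smallest it can give here, for SL RNA, snRNA, snoRNA, tRNA, protein-coding, other non-coding and piRNA genes. The adjusted p was 0.0127 for microRNA genes, 0.0413 for pseudogenes and 1 for ribosomal RNA genes. With overlap of the peak interval and the gene body in place of a summit near the start, the protein-coding value was 0.846-fold. With piRNA genes in tandem counted as a locus, 40 of 1835 were bound (0.591-fold). In simulated data with peaks planted at other classes, piRNA genes were also called below rotation. The folds of SL RNA, snRNA, snoRNA and tRNA genes were 103.9, 91.8, 45.1 and 31.6 within 100 bp and 23.9, 19.7, 12.3 and 8.27 within 500 bp.

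**Figure D1:**
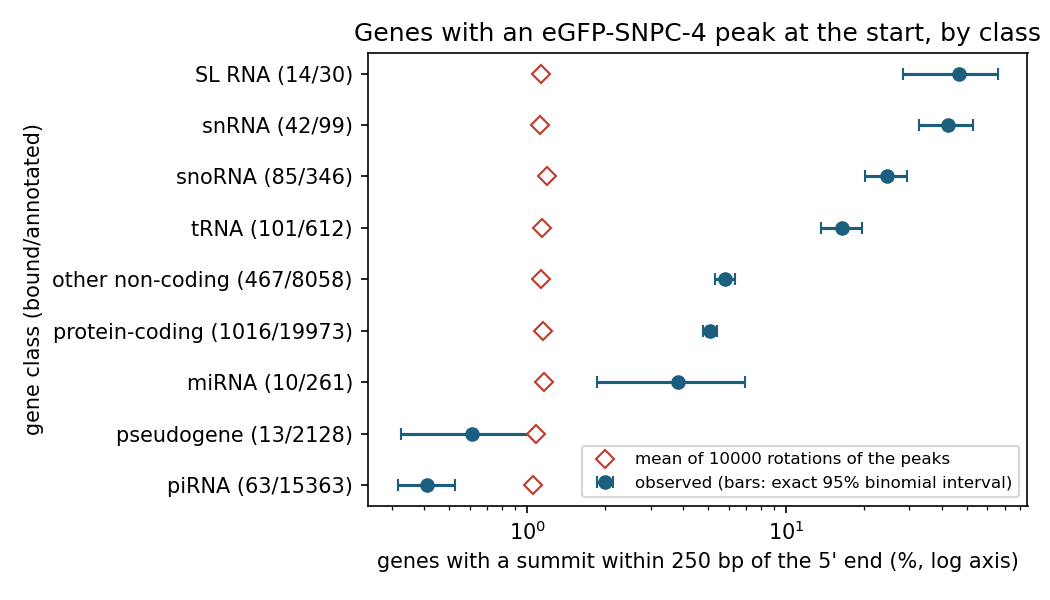
Share of genes of each class with a thresholded summit within 250 bp of the 5′ end, in percent on a log axis; filled points are observed shares with exact 95% binomial intervals and open diamonds the mean of 10000 rotations of the peaks. SL RNA (46.7%) and snRNA genes (42.4%) stand highest, and piRNA genes lie below their rotation mean; ribosomal RNA genes, with 0 of 20, are not drawn.

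The relaxed peaks that did not pass the authors' threshold gave a background from the same libraries. Near snoRNA starts lay 3.67% of thresholded and 0.228% of the remaining 27652 nuclear relaxed peaks, and near snRNA starts 1.77% and 0.0940%. Near tRNA starts the shares were 4.05% and 0.998%, and near SL RNA starts 0.647% and 0.0145%. Protein-coding starts had 36.3% of thresholded and 11.8% of relaxed peaks nearby. The piRNA starts went the other way, with 1.81% of thresholded and 5.16% of relaxed peaks. Fisher's exact test, two-sided and Benjamini-Hochberg adjusted over 10 classes, gave adjusted p = 9.72e-55 for snoRNA, 1.77e-28 for snRNA, 4.03e-25 for tRNA, 8.40e-14 for SL RNA, 2.84e-182 for protein-coding and 1.42e-15 for piRNA genes. Pseudogenes did not differ (exact test, adjusted p = 0.989).

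Among the annotated types, SL2 genes were bound most often. A summit lay near 14 of 18 SL2 genes (77.8%, exact 95% binomial interval 52.4 to 93.6%). SmY genes, nematode snRNA genes with a role linked to trans-splicing, had 4 of 10 (40%) in the snRNA class, and the other snRNA genes 38 of 89 (42.7%). Near the 12 SL1 genes there was no summit, and no peak of the pooled relaxed list either. The median share of 36-base words around their starts that occur once in the genome was 0. Reads of 36 bases or fewer would then mostly have no unique place there. The read length and the handling of such reads are not known here, so a missing peak cannot be read as missing binding. SL1 genes were therefore left out of the tests after the data were seen. Fisher's exact test, Benjamini-Hochberg adjusted over the other 3 pairs of types, gave adjusted p = 0.0270 for SL2 against other snRNA genes, 0.146 for SL2 against SmY and 1 for SmY against other snRNA genes. Single-copy 36-base words around the start had a median share of 0.912 for SL2 genes. For the spliceosomal types assigned below, the medians ran from 0.625 (U2) to 0.784 (U5). Binding and the placing of reads were therefore not separated for SL2 against other snRNA genes. With the N highest peaks of replicate 1 alone SL2 against SmY passed (exact test, adjusted p = 0.0245). These counts leave out smy-2 and smy-3, which are bound (signal 2684 and 804) and annotated as snoRNA genes. With both, chosen after seeing the data, SmY had 6 of 12, and the exact test against SL2 gave adjusted p = 0.209.

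The annotation does not say which spliceosomal snRNA each gene encodes, so types were assigned by short conserved sequences after the peaks had been seen. U5 genes were bound most often, 10 of 11 (90.9%, exact 95% binomial interval 58.7 to 99.8%), then U1 with 8 of 12 (66.7%). For U4 the count was 2 of 5 (40%), for U2 7 of 19 (36.8%) and for U6, the snRNA made by RNA polymerase III, 8 of 22 (36.4%). By Fisher's exact test, adjusted over 15 pairs, U5 exceeded U2 and U6 (adjusted p = 0.0252 for each), and U1 did not differ from U6 (adjusted p = 0.276). Neighbouring copies, as among the bound U5 genes of chromosome IV, count as separate genes in this test, and tandem copies were not merged for these pairs. Around their starts the median share of single-copy 36-base words was 0.784 for U5, 0.625 for U2 and 0.663 for U6 genes. It was 0.445 for the 14 unbound U6 genes and 0.709 for the 8 bound ones, and for U2 0.638 unbound and 0.621 bound. The test of U5 against U6 therefore does not separate binding from the placing of reads. Of 20 snRNA genes without a single type 3 were bound, fewer than for U5 (exact test, adjusted p = 0.000926). The median signal at bound genes was 1635 for the 2 U4 genes, 351 for U6, 322 for U1, 93.8 for U5, 72.5 for U2 and 1342 for those without a type. Of these 3, mir-1831 shares the peak of the U1 gene sup-39, which is the median, and T27E4.22 that of the U1 gene T27E4.12.

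The strongest peaks fell just upstream of named small RNA genes. The highest, with signal 6125, had its summit 55 bp upstream of W05B2.8 (III:10989679-10989780, plus strand), in an intron of a protein-coding gene. The second (6107) lay 85 bp upstream of the snoRNA gene Y53F4B.47 (II:15025814-15025893, minus strand) and the third (5955) 55 bp upstream of sls-2.4 (I:4172206-4172315, plus strand), both in intergenic sequence. Among the 25 highest were also the SL2 genes sls-2.8 (4725), sls-2.1 (3816) and sls-2.2 (3589), the U4 gene C52E4.8 (3166) and the U5 gene F38E11.10 (2936). The peak of signal 3960 had its summit 55 bp upstream of sup-6, a U1 gene (II:12944803-12944967, minus strand), and inside the non-coding gene F58G1.11. The snoRNA genes ZK994.7 (5205), F01D5.12 (3674), F59C6.15 (2738), C08D8.3 (2727), C16D9.11 (2572), T26A8.6 (2529) and Y55F3BR.9 (2494) stood in the same set, as did smy-2 (2684), which is annotated as a snoRNA gene. The peak of signal 4646 lay inside the non-coding gene Y37E3.29 and 56 bp upstream of the snoRNA gene Y37E3.20.

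Other non-coding RNA genes also had strong peaks. The summit at rpr-1, the RNA of ribonuclease P, lay 25 bp upstream of the gene (I:13463955-13464207, plus strand) with signal 4721 in the thresholded list, 1806 in replicate 1 and 2945 in replicate 2. At mrpr-1, the RNA of ribonuclease MRP (II:7200233-7200418, plus strand), it lay 37 bp upstream with signal 2495. K11H12.t1, the selenocysteine tRNA gene (IV:658181-658266, plus strand), had the highest peak of all nuclear tRNA genes, 57 bp upstream with signal 2230 and rank 27. The median over all bound tRNA genes was 50.8. F08G2.13 (3759, 56 bp upstream) and W01D2.7 (2728, 46 bp upstream) are annotated only as non-coding RNA genes on chromosome II.

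The next comparison asked where the summit lies relative to the gene start. At snRNA, SL RNA and snoRNA genes it lay upstream, with a median offset of -55 bp for 42 snRNA genes (quartiles -60.5 and -48.2), -53 bp for 14 SL RNA genes (quartiles -57.8 and -46) and -56 bp for 85 snoRNA genes (quartiles -79 and -43). Of these genes 38 (90.5%), 14 (100%) and 79 (92.9%) had the summit upstream. The tRNA genes, which have promoters inside the gene, had a median of -27 bp (quartiles -42 and 1), with 74 of 101 upstream. Protein-coding genes had a median of -139 bp (quartiles -181 and -62), with 940 of 1016 upstream. These are distances from the annotated 5′ end, and whether transcription starts there was not examined. For piRNA genes 29 of 63 lay upstream. The exact two-sided binomial test against equal numbers, adjusted over the 9 classes with a bound gene, gave adjusted p = 1.27e-07 for snRNA, 0.000183 for SL RNA, 7.32e-17 for snoRNA, 3.00e-06 for tRNA, 4.16e-190 for protein-coding and 0.615 for piRNA genes. Genes of the other non-coding class had the summit downstream, at a median of 66 bp with 139 of 467 upstream (exact test, adjusted p = 5.02e-18). Genes that share a peak count separately in this test. The 1016 protein-coding genes rest on 842 peaks, so p-values for such classes are too small.

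**Figure D2:**
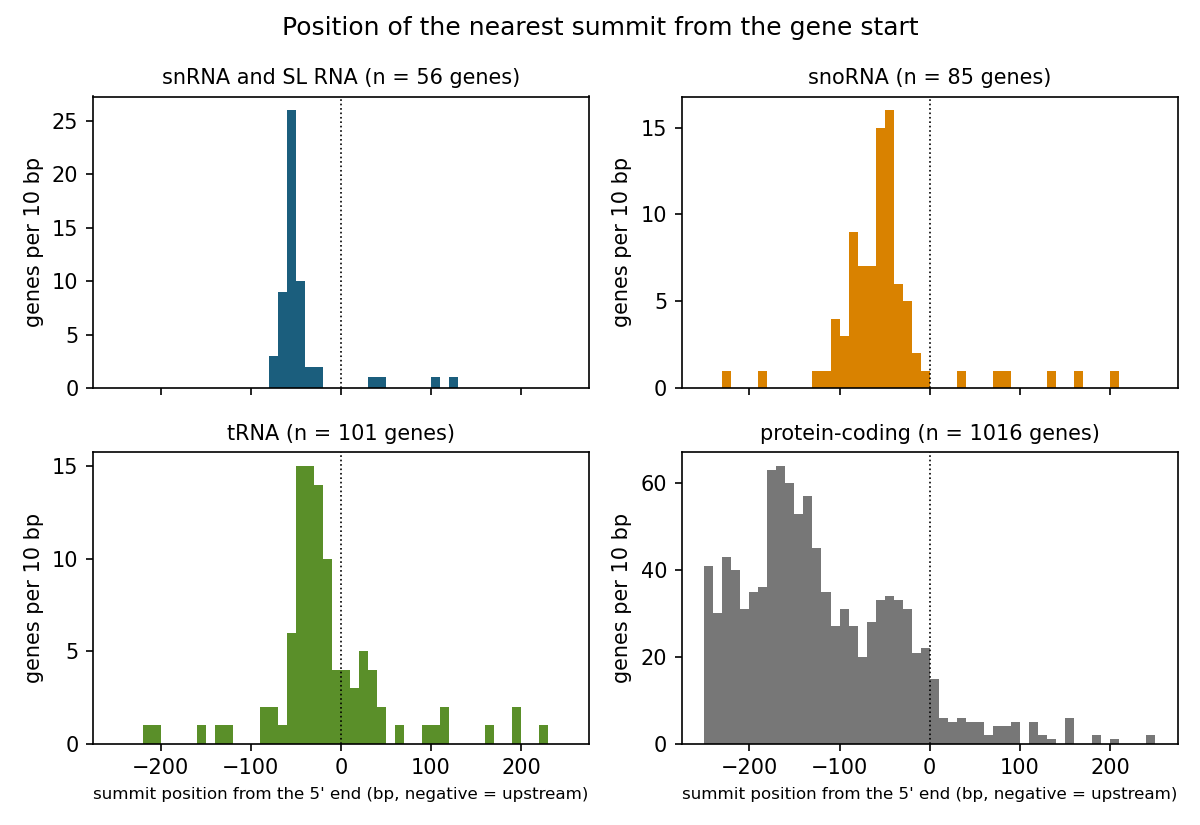
Number of genes per 10 bp by position of the nearest summit from the 5′ end, in bp with negative values upstream, for snRNA and SL RNA (56 genes), snoRNA (85), tRNA (101) and protein-coding genes (1016). The first 2 groups have their medians near -55 bp, tRNA genes lie nearer to the start with a median of -27 bp, and protein-coding genes spread over the upstream 250 bp.

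The kind of gene near a peak changed with rank. Of the 50 highest nuclear peaks, 39 (78%) lay within 250 bp of a snRNA, SL RNA or snoRNA start, and of the next 50, 16 (32%). The share was 6% at ranks 101 to 200 and 3.49% from rank 1001 on. Protein-coding starts with no small RNA start nearby took 2% of the 50 highest peaks, 34% at ranks 101 to 200 and 43.3% at ranks 201 to 500. Peaks near SL RNA starts had a median signal of 820.3, near snRNA starts 117, near snoRNA starts 67.5 and near tRNA starts 48.6. Over all small RNA classes the median was 60.4 for 276 peaks against 51.9 for the other 2043 (permutation test with 100000 resamples, two-sided, p = 0.00029). With snRNA, SL RNA and snoRNA starts alone, chosen after seeing the data, the medians were 96.0 and 51.7 (permutation p = 1e-05, the smallest it can give). Over all small RNA classes with the signal of replicate 1 alone, the medians were 27.6 for 269 peaks and 25.1 for 1950 (permutation test, p = 0.039).

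**Figure D3:**
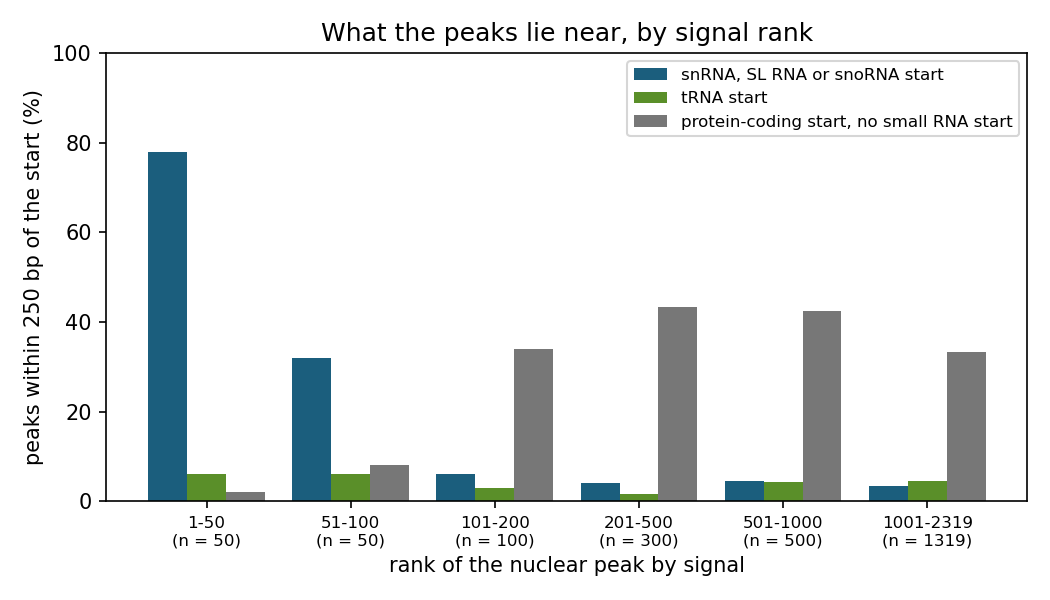
Percent of nuclear thresholded peaks within 250 bp of a snRNA, SL RNA or snoRNA start, a tRNA start, or a protein-coding start with no small RNA start, in 6 bins of rank by signal (peaks per bin under the axis). The first group falls from 78% of the 50 highest to 3.49% beyond rank 1000, and the protein-coding group reaches 43.3% at ranks 201 to 500.

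SNPC-4 is known to occupy the piRNA clusters of chromosome IV in the germline, and L1 larvae hold few germ cells. In these larvae the clusters had no excess of peaks. The 2 domains, the first from 4.5 to 7.0 Mb and the other 3.7 Mb long, starting 6.5 Mb beyond its end, held 126 of the 369 chromosome IV peaks (34.1%), with 35.4% of its length. Rotation of the chromosome gave a mean of 130.8 (0.963-fold, two-sided permutation p = 0.569). In the pooled relaxed list 2170 of 5586 peaks fell inside (1.10-fold, permutation p = 0.0668). The domains contain 14204 of the 15363 annotated piRNA genes (92.5%), of which 48 had a summit within 250 bp. The strongest peak near a piRNA start, at 21ur-10179 and 21ur-7591 (signal 1170), had its summit 228 and 225 bp downstream of their starts, beyond these short genes and 67 bp upstream of the snoRNA gene Y67A10A.14. Of the 63 piRNA genes with a summit, 16 share it with a snRNA, SL RNA, snoRNA or tRNA gene. At 21ur-14429 it lay 202 bp downstream with signal 195.

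Among microRNA genes the strongest peaks were at mir-2214 (III:7278715-7278778; signal 1117, 44 bp upstream), mir-8196.1 (714, 57 bp upstream) and mir-5549 (174, 12 bp upstream). The last peak also lies 385 bp upstream of eef-1A.1. After K11H12.t1, the strongest peaks at tRNA genes were at M01E5.t1 (1040), where the summit is also 61 bp upstream of sls-2.9, and at C27A2.t1 (832, 18 bp upstream).

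The sequence at the summits was compared with flanks 500 bp away. The piRNA upstream core CTGTTTCA was within 50 bp of 5 summits, fewer than the 17 and 18 of the flanks (exact McNemar tests, adjusted p = 0.0338 for each), and this did not pass with the peaks of replicate 1 alone. The tRNA B box GTTCRANNC, part of the promoter inside tRNA genes, was at 56 summits against 44 and 59 (exact tests, adjusted p = 0.349 and 0.851). At bound tRNA genes the median summit offset was -27 bp, so a window of 50 bp covers only the first part of most of these genes. It can miss a B box further inside, so these counts do not decide whether tRNA peaks carry one. Within 100 bp in place of 50, the B box was 1.53-fold above its flanks (exact test, adjusted p = 0.0127). The 8-base words most enriched on chromosomes I, III and V were then tested on II, IV and X, where all 10 passed (exact McNemar test, adjusted). AGACGCAG was at the summit alone in 105 of these test peaks and at the flank alone in 4 (exact test, adjusted p = 5.94e-26), and CGGAACCC in 94 and 1 (adjusted p = 2.42e-26).

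A matrix of 20 bases was learned, after the words had been seen, from the 100 bp upstream of 65 bound snRNA, SL RNA and snoRNA genes on I, III and V. Its most frequent bases read GGTCGGCGGAACCCGCGAGG, and its median position was -68 to -49 bp. On II, IV and X a match lay within 50 bp of the summit at 153 of all 1147 peaks (13.3%), and at 59 of the 659 from rank 1001 on (8.95%). It was at 34 of 69 peaks near snRNA, SL RNA or snoRNA starts (49.3%) and at 0 of their flanks (exact McNemar p = 1.16e-10 for each). Near tRNA starts only 1 of 61 peaks (1.64%) had one, and near protein-coding starts 27 of 505 (5.35%). AGACGCAG was distributed the other way, at 52 of those 505 protein-coding peaks (10.3%) and 2 of the 69 (2.90%; Fisher's exact p = 0.0479). No peak of either kind had both. At sup-6 the match was GAGCGGCGGAACCCGCCACA (II:12945013-12945032), 65 to 46 bp upstream, and at F38E11.10 it was GACCCGCGAAACCCGCAAGA (IV:9444574-9444593). Of 18 SL2 genes, including those the matrix was learned on, 13 (72.2%) had a match upstream, and sls-2.1, sls-2.2 and sls-2.4 had none above the threshold.

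The last comparison asked which protein-coding genes had a peak, over 20 lists of genes fixed before the data were examined. Of these, 5 lists stood highest. A summit lay within 500 bp of a start for 48 of 64 ribosomal protein genes (75%), 20 of 33 proteasome genes (60.6%), 10 of 19 genes for spliceosomal snRNP proteins (52.6%), 19 of 38 translation factor genes (50%) and 20 of 41 genes of mitochondrial oxidative phosphorylation (48.8%). Over all protein-coding genes it was 1668 of 19973 (8.35%). Fisher's exact test, two-sided and adjusted over the 20 lists, gave adjusted p = 1.21e-37, 3.23e-13, 2.45e-06, 8.90e-11 and 5.92e-11 in that order. With peaks near snRNA, SL RNA, snoRNA and tRNA starts left out, 41 of the 64 ribosomal protein genes and 20 of the 33 proteasome genes still had one. Within 250 bp the excess of ribosomal protein genes over other genes was 8.67 percentage points (exact test, adjusted p = 0.0183), against 66.9 within 500 bp. For snRNP proteins, translation factors and oxidative phosphorylation it was 26.2, 26.2 and 23.9 points, against 44.3, 41.7 and 40.5.

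Named members of these lists had peaks of moderate height. Among ribosomal protein genes the highest were at rpl-15 (signal 465, 354 bp upstream), rpl-3 (266), rps-19 (220) and rpl-35 (194). Among proteasome genes they were at rpt-1 (202, 125 bp upstream), pas-5 (150), rpn-3 (126) and rpt-2 (102), and among translation factors at eif-3.B (253), eif-3.C (195), eef-1A.1 (174) and iff-2 (145). The respiratory chain genes cox-5A (207), cox-6B (147), atp-1 (134) and cox-5B (122) followed. In the snRNP list the peak at snr-4 (3166) is that of the U4 gene C52E4.8, and snrp-3 (69.7), snrp-40.1 (64.8) and snr-3 (58.8) were lower.

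RNA polymerase II subunits and general factors had 9 of 40 genes with a peak (22.5%, exact test, adjusted p = 0.0117), among them rpb-11 (195), taf-4 (89.2), taf-11.3 (66.4) and rpb-10 (58.8). With the peaks of replicate 2 alone this list did not pass (exact test, adjusted p = 0.178). Heat shock and stress genes had 13 of 80 (16.2%, exact test, adjusted p = 0.0375), with hsp-90 (135), hsp-110 (126, the same peak as rpn-3), hsp-16.20 and hsp-16.21 (117 for both, a single peak that is also upstream of the U1 gene F08H9.10). With the peaks of replicate 1 alone that difference did not pass (exact test, adjusted p = 0.383), nor did it without peaks near tRNA, snRNA and SL RNA starts (0.148) or within 250 bp (0.5002).

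Chemoreceptor, neuropeptide, homeobox, collagen and nuclear hormone receptor genes had a peak less often than other protein-coding genes. Chemoreceptor genes had 9 of 1367 (0.658%, exact test, adjusted p = 3.67e-39), neuropeptide genes 2 of 147 (1.36%, 0.00134), homeobox genes 1 of 87 (1.15%, 0.0179), collagen genes 5 of 175 (2.86%, 0.0117) and nuclear hormone receptor genes 11 of 274 (4.01%, 0.0117). Against rotated peaks in place of other genes, chemoreceptors remained below (permutation by rotation, 0.318-fold, adjusted p = 0.00100), and the other 4 lists did not pass (adjusted p from 0.290 to 0.881). Of these, collagens (1.21-fold) and nuclear hormone receptors (1.57-fold) then lay above rotation. With the peaks of replicate 1 alone nuclear hormone receptors did not pass (exact test, adjusted p = 0.0533), and within 250 bp neuropeptides (0.0517) and homeobox genes (0.142) did not. The members with the highest peaks were srh-16 (118), sri-5 (106) and srh-269 (62.3, also 43 bp upstream of the tRNA gene T03E6.t1) among chemoreceptors, nlp-4 (228) and ins-37 (36.9, a peak inside the U2 gene F08G2.9) among neuropeptides, and ceh-38 (195) among homeobox genes. For collagens they were col-85 (146, also 43 bp upstream of the tRNA gene T21B4.t1), col-38 (115.1), col-71 (59.8) and col-72 (36.5), and for nuclear hormone receptors nhr-212 (117), nhr-47 (91.1), nhr-114 (88.1) and nhr-49 (60.4).

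The remaining lists did not pass by Fisher's exact test. RNA polymerase I and III subunits had 3 of 15 (rpoa-1, tftc-1 and rpac-19, exact test, adjusted p = 0.178), neuron markers 4 of 24 (unc-33, unc-31, snb-1 and egl-21, 0.181; the unc-31 peak is also inside the U5 gene ZK897.4), aminoacyl-tRNA synthetases 5 of 32 (with ears-2, kars-1, mars-1 and fars-3, 0.232) and histones 10 of 81 (with his-37, htz-1, hil-7 and his-24, 0.261). Germline markers had 5 of 48 (with syp-4, puf-9, syp-3 and nos-3, 0.663; the syp-4 peak is also 52 bp upstream of the U1 gene H27M09.6), body wall muscle markers 2 of 21 (unc-112 and act-4, 0.723) and intestine markers 0 of 40 (0.117). Of 27 SNAPc and piRNA pathway genes, 1 had a peak, snpc-3.4 with signal 38.6 (exact test, adjusted p = 0.723). The peaks at snpc-3.4 and act-4 (signal 35.4) had no summit within 100 bp in the relaxed list of replicate 1. The peak at mars-1 (37.7) had none in that of replicate 2. Against rotated peaks, histones (permutation by rotation, 5.74-fold, adjusted p = 0.00578), synthetases (4.59-fold, 0.0184), RNA polymerase I and III subunits (7.58-fold, 0.0247) and neuron markers (4.93-fold, 0.0320) passed. Protein-coding genes as a class were themselves 3.51-fold above rotation within 500 bp of the gene start. Passing against rotation therefore does not set these lists apart from other protein-coding genes. With the peaks of replicate 1 alone, synthetases (exact test, adjusted p = 0.00724) and RNA polymerase I and III subunits (0.0498) did.

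**Figure D4:**
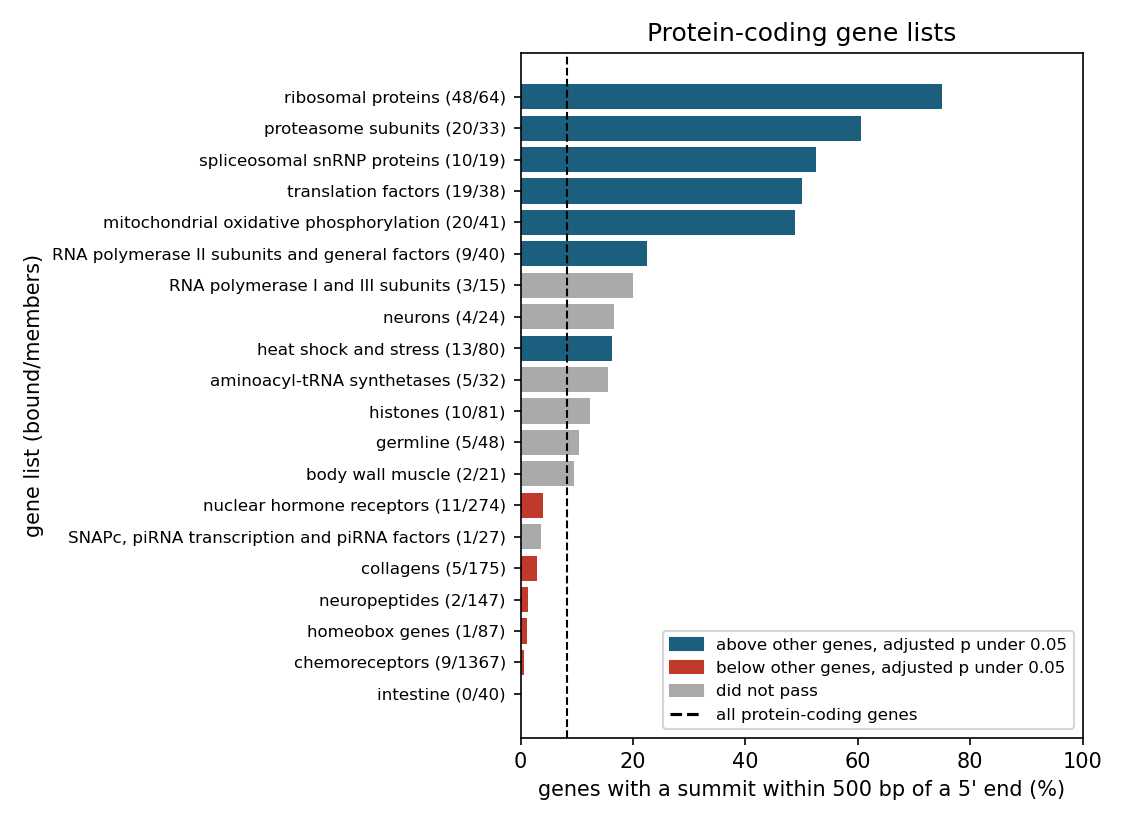
Percent of genes in each of 20 protein-coding lists with a thresholded summit within 500 bp of a 5′ end (bars; bound and total members beside each name), with the share of all protein-coding genes as a dashed line at 8.35%. Ribosomal protein genes reach 75% and chemoreceptor genes 0.658%; colours mark lists above, below or not different from other genes by Fisher's exact test at an adjusted p of 0.05.

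The 2 genes carried by the transgene had no peak at their starts. The nearest thresholded summit lay 89030 bp from the start of snpc-4 (I:8962322-8966129) and 6622 bp from that of unc-119 (III:10902641-10908935; signal 39.2). Within 20 kb of snpc-4 the pooled relaxed list had 1 peak, where its mean density gives 13.1, and within 20 kb of unc-119 it had 24, where 13.8 are given.

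By chromosome, peaks per length were above the nuclear mean on III (384 peaks, 1.20-fold) and I (413, 1.18-fold) and below it on V (375, 0.775-fold). The exact binomial test, adjusted over 6 chromosomes, gave adjusted p = 0.000379, 0.000498 and 6.91e-08. Chromosomes II (1.10-fold), IV (0.912-fold) and X (0.949-fold) did not pass. With the peaks of replicate 1 alone II (1.19-fold, exact test, adjusted p = 0.000349) and IV (0.902-fold, 0.0370) did. Peaks close together are not independent, so these p-values are too small. Against the remaining relaxed peaks in place of length, III did not pass (1.04-fold, exact test, adjusted p = 0.546).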

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

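The mitochondrial genome, which the comparisons of genes leave out, held 28 thresholded peaks, or 2.03 per kb against 0.0231 per kb on the nuclear chromosomes. Of these, 17 were among the 100 highest peaks of the list. The strongest ranked 8 with signal 4147, and its summit at position 4753 lies inside an annotated protein-coding gene (4504-5621). It ranked 4 in replicate 1 and 12 in replicate 2. No level in the control alignment was analysed here, so whether these peaks differ from the control was not tested.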

How the results depend on the processing

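Of 420 values recomputed under an alternative, 354 kept their direction and side of the threshold, 29 no longer passed, 14 newly passed and 22 turned in direction. Those that turned had not passed before, except protein-coding genes by gene body and the collagen and nuclear hormone receptor lists against rotation. The replicate correlation moved to 0.707 over all relaxed peaks. The cause of these changes was not tested. The 354 include values without a p-value, those of the snRNA types by sequence and of the replicate correlation. They also include ribosomal RNA genes, where no gene was bound in any setting. This number therefore overstates how many values were put to a threshold they could cross. Values for SL1 count near-identical copies as separate genes. The planned pairs with SL1, left out of the tests in the results, are still counted among these 420 values, and nothing is concluded from them. The fold for snRNA, SL RNA, snoRNA and tRNA genes kept its direction and passed under every alternative run. Counted by gene body, protein-coding genes turned to 0.846-fold of rotation. Against relaxed peaks, chromosomes II (1.23) and IV (0.843) newly passed and III (1.04) no longer did. In the relaxed list the piRNA domains turned to 1.10-fold.

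In the upper part of the list by signal, calls ended for microRNA genes (3.35-fold), pseudogenes (0.682-fold), the piRNA core (0.25), the offsets of microRNA genes and pseudogenes (-57 and -140 bp), microRNA genes against relaxed peaks (0.269 points), SL1 against SmY (-20), polymerase II factors (5.54), collagens (-2.78), homeobox genes (-3.34) and nuclear hormone receptors (-2.68). Chromosome II (1.16) and SL2 against SmY (52.2) newly passed. Pseudogenes against relaxed peaks (0.0706 points), the piRNA offset (-43 bp) and the B box (0.759) turned. This set has fewer peaks.

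With a 100 bp window, calls ended for pseudogenes (0.430-fold) and the offsets of microRNA genes (-44 bp) and pseudogenes (-17 bp). The piRNA offset turned to -50.5 bp there and to -56 bp at 500 bp, where SmY against other snRNA genes turned to 7.30 points, as it did with the SmY genes annotated as snoRNA included. Within 25 bp the piRNA core no longer passed (0.105) and the B box turned (0.977), as it did without peaks near tRNA starts (0.808). Within 100 bp the B box newly passed (1.53). With 250 bp for lists, calls ended for neuropeptides (-4.09), homeobox genes (-4.29) and heat shock genes (2.09), and muscle turned to -0.656, and to -1.26 at 1000 bp. The heat shock call also ended without peaks near tRNA, snRNA and SL RNA starts (5.62). Against rotated peaks histones (10.2), polymerase I and III (17.4), synthetases (12.2) and neurons (13.3) newly passed, collagens (0.492), nuclear hormone receptors (1.46) and the SNAPc list (1.16) turned, and neuropeptides (-1.16) and homeobox genes (-1.996) no longer passed.

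With each replicate left out in turn, values ranged from 1.09 to 1.19 for chromosome II, 0.902 to 0.936 for IV, 0.912 to 1.01 for X, 0.278 to 0.438 for the piRNA core and 0.939 to 0.990 for the B box. Offsets ranged from -68 to -62 bp for microRNA genes, -147.5 to -147 bp for pseudogenes and -44 to 85 bp for piRNA genes. Differences ranged from -50 to -20 points for SL1 against SmY, 27.8 to 52.2 for SL2 against SmY, -18.2 to 8.43 for SmY against other snRNA genes, 11.97 to 18.5 for polymerase I and III, 6.97 to 16.8 for polymerase II factors, 4.47 to 16.8 for synthetases, -4.45 to -3.53 for nuclear hormone receptors, -1.98 to 2.38 for germline genes, 1.66 to 1.84 for histones, -0.820 to -0.634 for the SNAPc list, 1.30 to 6.25 for muscle and 3.04 to 10.8 for heat shock genes. Without replicate 2, chromosomes II and IV, SL2 against SmY, polymerase I and III and synthetases newly passed. Calls ended there for the offsets of microRNA genes and pseudogenes, SL1 against SmY, the piRNA core, nuclear hormone receptors and heat shock genes. The distribution over chromosomes on build ce10 was not run, since no ce10 sequence lengths were used here. Depth is unknown, so whether genes without a peak lacked binding or lacked reads could not be separated.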

Other observations

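Some of the strongest peaks have no annotated non-coding gene start nearby. Of the 200 highest nuclear peaks, 100 had no non-coding 5′ end within 500 bp, and for 45 of these there was no protein-coding 5′ end within 500 bp either. The highest, with signal 1719 and rank 34, has its summit at I:13859257, in an intron, 2211 bp from the start of taf-1. Others are at III:11464010 (880), V:20455843 (819) and II:12778565 (555). They were chosen after their values were seen, and the types of snRNA and the matrix were also chosen after the peaks had been seen. Of the tests below, those of shared reads at SL1 genes and of AGACGCAG at protein-coding genes were chosen after the result was seen. No biological explanation could be tested against another group, since the design has 1.

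Genes of the snRNA and SL RNA classes without a peak are the first pattern. On chromosomes II, IV and X a match to the upstream matrix lay within 100 bp of the start for 20 of 27 bound genes (74.1%) and 9 of 33 unbound genes (27.3%, Fisher's exact p = 0.000607). Copies that lack the element may therefore be among those without a peak. A match was not needed for a strong peak, since sls-2.1 and sls-2.2 on chromosome II had none above the threshold and ranked 10 and 13. Reads shared between copies stay open too, since the median share of single-copy 36-base words around the start was 0.654 for 73 unbound genes and 0.789 for 56 bound ones, between the bounds set for either outcome, and 0.767 for unbound genes without the 12 SL1 genes. Unbound genes had lower medians than bound ones for U6 (0.445 for 14 and 0.709 for 8) and U1 (0.322 for 4 and 0.759 for 8). They had higher ones for U2 (0.638 for 12 and 0.621 for 7) and U4 (0.767 for 3 and 0.731 for 2). For U5 the 1 unbound gene had 0.907, and the 10 bound ones had a median of 0.779. At the 12 SL1 genes the median share of single-copy 36-base words was 0, so reads shared between near-identical copies remain possible there. Copies lacking the upstream element, with 0% having a match, also remain possible for SL1. The copies are nearly identical, so this is close to a single observation.

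Peaks at protein-coding gene starts are the second pattern. Only 85 of the 1668 bound protein-coding genes, a share of 0.0510, had a snRNA, SL RNA, snoRNA or tRNA start within 500 bp of the summit, which argues against neighbouring small RNA genes as the source of most of them. A match to the matrix was at 4.73% of the 1185 such peaks with no small RNA start nearby, against 1.27% and 1.35% in the flanks, so a small part may carry the element while enrichment without it stays open for the rest. A second promoter sequence remains possible: on II, IV and X, AGACGCAG was at 10.3% of these peaks and at 0.594% of each flank. The flanks lie 500 bp away and protein-coding starts without a peak were not compared. The word may therefore mark such starts whether or not they have a peak. Whether SNPC-4 binds there or open promoters are enriched in general could not be tested, as 4.73% decides neither and no other factor was profiled.

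The strong peaks without an annotated non-coding start are the third pattern. Within 150 bp of the 100 summits the median share of single-copy 36-base words was 1, and none was below 0.5. These summits thus lie mostly in sequence that occurs once in the assembly. The handling of reads without a unique place is not known here. If they were left out, any peak would tend to lie in such sequence, so the share does not decide on repeated sequence as a cause. Unannotated genes with the upstream element could account for some, as 24.0% had a match within 50 bp, against 80.3% of the 61 peaks of the same set near snRNA, SL RNA or snoRNA starts, which include the genes the matrix was learned on. Among the 45 with no gene start of any kind within 500 bp it was 17 (37.8%), and among the other 55 it was 7 (12.7%). The summits at I:13859257 and III:11464010 had one, and those at V:20455843 and II:12778565 had none.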
